A study of Mus musculus with 2 samples.

How the data were processed

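Total RNA from primary mouse osteoblasts was compared between 1 untreated culture and 1 culture given TGF-beta1 at 2 ng/ml for 24 h. Both cultures were held in alphaMEM with 0.2% fetal bovine serum, a serum-starved condition. Per the labels' protocols, RNA was extracted with TRIZOL, cDNA was labelled with the BD Atlas fluorescent kit, and both samples carried Cy3. Each sample therefore stood on an array of its own with 1 colour. The labels put 1 sample in each group, so no spread between replicates was measured, no test was run and no p-value is given.

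The deposited spot intensities were on a linear scale and had been put through a normalization named global, per the file headers. The background had been subtracted before deposit as far as the values show, since 3 treated intensities lay below 0. The way the background was estimated, the scanner and the image software are not given in the sources used here. Per the file headers, the workbook of the study was made with Atlas Iris 1.01 for the Atlas Glass Mouse 3.8 array. The authors' deposited ratio of each spot was the treated over the untreated intensity, and 3754 of 3754 ratios matched the quotient of the deposited intensities within 0.0001. A further 3 probes had no deposited ratio. The array carried 3774 spots, of which 17 control spots had no probe identifier and were left out, which left 3757 probes with 1 spot each. In 8 sheets of the workbook 16 columns of per-sample values carried names that matched no sample label, and these columns were not used.

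The authors' signal threshold was the brightest of the lambda phage control spots, 87.4, where the mean of the lambda spots was 67.0, per the file headers. Each lambda signal was a mean of both arrays, so a lambda spot could exceed the threshold on 1 array. The brightest one, with a ratio of 1.18, did so on the treated array. Genes only slightly above 87.4 are therefore not clearly set apart from the control spots. A probe above this threshold on an array was taken as detected there, and the authors' flags followed from this rule for 3757 of 3757 probes. The main value of a gene was the log2 of the treated over the untreated deposited intensity with nothing added. A gene was counted as higher or lower on the treated array when it was above the threshold on both arrays and its ratio was at least 2-fold. For a gene above the threshold on 1 array only, a lower bound of the fold was computed. It was the bright signal over the higher of the gene's own dim signal and the lowest signal above the threshold on the dim array. Every value rests on 1 spot per array, and the number of arrays limits the precision. The only repeated measure within the arrays was the set of 8 lambda spots, whose log2 ratios had an SD of 0.20. These spots were dim and lay in 1 block, so this SD is a rough scale and not an error of any gene.

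Probes were named through the unversioned accession beside each spot and a table of mouse genes of assembly GRCm38.p6, which served for names only. A symbol was found for 3597 probes, none had several, and 160 kept the name in the file, of which 43 were above the threshold on at least 1 array. The 3 symbols that stood on 2 probes were under the threshold throughout, so probes of a gene were never combined. The files name no genome build, and no coordinates are given.

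Before the data were examined, 25 gene lists for osteoblasts, TGF-beta signalling, matrix, general cell functions and other cell types were fixed. The rule for genes named in the text was fixed at the same time. Among genes above the threshold on both arrays it took the 12 highest and the 12 lowest log2 ratios. Of genes above it on 1 array it took the 5 largest bounds in each direction. From each list it took up to 4 detected members with the largest absolute log2 ratio, and it added Smad7, Ccn2, Col1a1, Alpl, Bglap, Runx2, Spp1 and Acta2 whatever their values. Some genes that the rule also took are not reported here. A gene named outside this rule is said to have been chosen after its values were seen. For the 8 lists with at least 5 members above the threshold on at least 1 array, the median log2 ratio was placed among 10000 random lists of the same size. Random members were drawn from detected probes in 10 bins of mean log2 signal. The resulting percentile describes these 2 arrays and is not a p-value.

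The alternatives fixed in advance were quantile normalization, division by the median of detected probes, division by the total signal, and loess of the log2 ratio on mean log2 signal with a span of 0.4. They also held an offset of 96.7 added to every signal, which was the 10th percentile of the detected signals, the authors' deposited ratio, other size thresholds and other filters on dim probes. After the data showed a pattern by place on the array, 3 position adjustments were added. In the first, the median log2 ratio of the probe's block was subtracted. In the second, the median of its neighbours within 2 rows and 2 columns was subtracted, and in both the overall median was added back. In the last, the block's median dim signal was subtracted from each array's signals. Under these adjustments the lowest detected signal used for a bound was taken after the adjustment, and it could lie under the threshold. Values without blocks B4 to F4, and list members at their bound, were added as well. The procedure was tested on simulated data with a noise SD of 0.20 for the comparison of treated and untreated signals over 3757 probes. Of simulated genes changed by 1.5 on the log2 scale, 100% of the 60 above the threshold on both arrays were called, and 66.7% of all 96. For a change of 2 the shares were 100% of 66 and 77.9% of 104, and 0% of unchanged genes were called. The simulation held no effect of place, and its noise was smaller than the SD of 0.44 of the measured log2 ratios. The 0% therefore gives no rate of false calls for these arrays. Of 100 unshifted random lists of 12 genes, 8 lay under the 5th or above the 95th percentile. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.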

Results

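Gene expression was profiled in primary mouse osteoblasts, the bone-forming cells, after 24 h with or without 2 ng/ml TGF-beta1, a growth factor stored in bone matrix. The study asked which genes respond to TGF-beta in these cells. There was 1 untreated and 1 treated sample, each on 1 array with 3757 probes. The summed signal was 427889 on the untreated array and 431093 on the treated array, with medians of 47.9 and 45.5. On the untreated array 924 probes (24.6%) exceeded the signal threshold set by the lambda control spots, and on the treated array 866 (23.1%) did. Both arrays had 795 probes in common above it, 200 probes exceeded it on 1 array only, and 2762 exceeded it on neither. There were no replicates, so every difference below is a difference between these 2 arrays and has no replicate check.

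Most detected genes had similar signals with and without TGF-beta1. Of the 795 genes above the threshold on both arrays, 673 (84.7%) lay within 1.5-fold, 12 were at least 2-fold higher on the treated array and 18 were at least 2-fold lower. Septin3, a cytoskeletal GTPase of the septin family, had the highest ratio in the deposited values, with 989 untreated and 3170 treated, a 3.21-fold difference. Clcn7, a lysosomal chloride transporter needed for bone resorption, had the lowest, with 370 untreated and 116 treated, 3.19-fold lower. Across genes, the log2 signals of the 2 arrays had a Pearson r of 0.935 over these 795 genes, which are not independent replicates, and the log2 ratio had a median of 0.03 and an SD of 0.44. The counts of 12 higher and 18 lower became 9 and 27 after loess, 16 and 15 after subtraction of the neighbours' median, and 1 and 3 when an offset was added to every signal. Similar counts did not mean the same genes. After subtraction of the neighbours' median, 7 of the 16 higher and 13 of the 15 lower were among the original calls. After subtraction of block medians, 9 of 15 higher and 13 of 17 lower were. At a ratio threshold of 2, the authors' deposited table of probes above the signal threshold on at least 1 array held 17 higher and 34 lower.

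**Figure D1:**
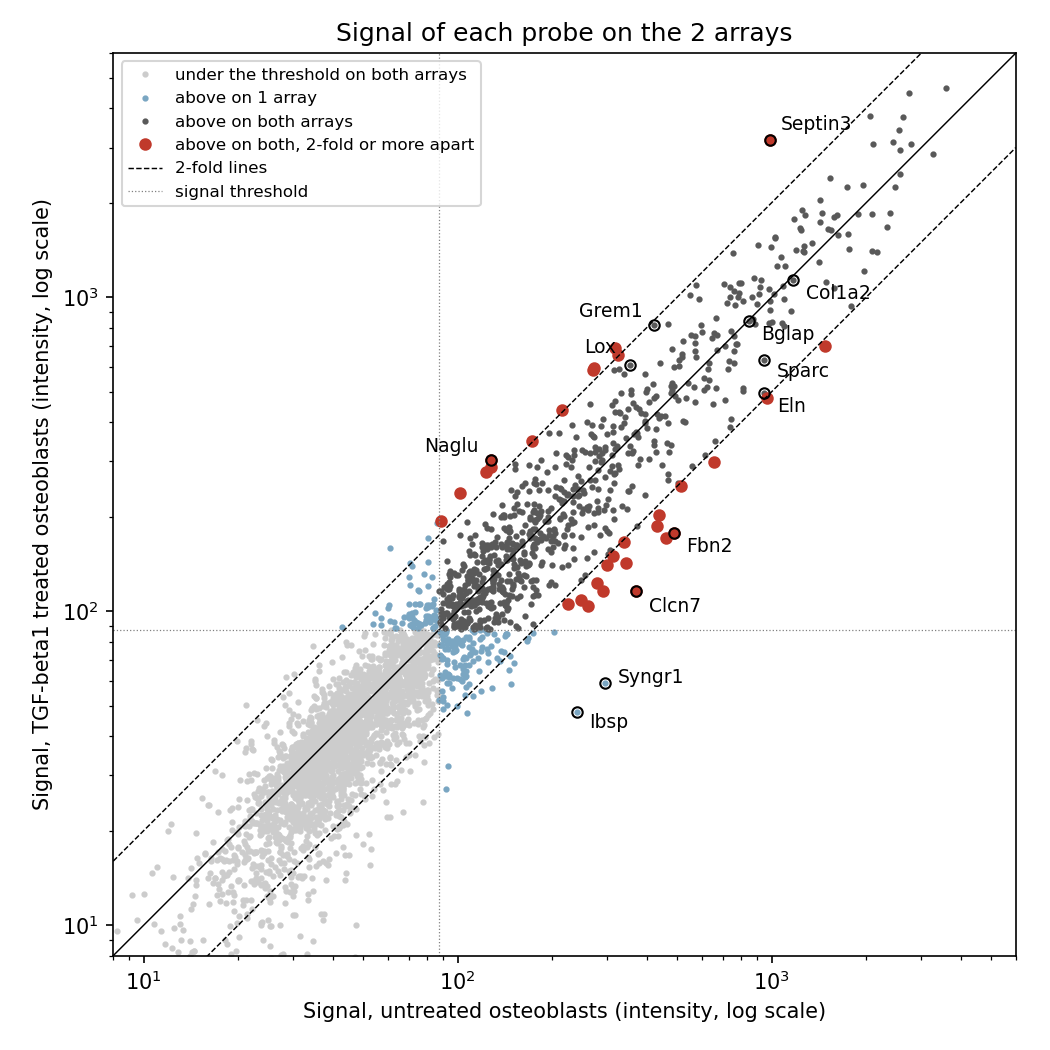
Signal of each probe on the untreated array (x axis) and the TGF-beta1 array (y axis), both as intensity on log scales from 8 to 6000, with 75 probes outside the axes. Each point is 1 probe; red points are the 12 genes at least 2-fold higher and the 18 at least 2-fold lower among those above the threshold on both arrays, dashed lines mark 2-fold, dotted lines the signal threshold of 87.4, and circles the named genes, with Septin3 farthest above the diagonal among the red points and Clcn7 farthest below.

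The other genes at least 2-fold higher with TGF-beta1 came from varied families. Probe sequences were not used, so whether each signal came from the named gene alone was not tested, here or below. Naglu, a lysosomal enzyme of heparan sulfate breakdown, was 2.37-fold higher, and Grn, the precursor of the granulin growth factors, was 2.19-fold higher. Stmn3, a microtubule regulator of the stathmin family, was 2.34-fold higher. The metalloprotease Adam25 was 2.26-fold higher and the keratin Krt12 was 2.25-fold higher. The fatty acid hydroxylase Cyp4a14 was 2.03-fold higher. These 6 genes and Septin3 stayed at least 2-fold higher under all 3 position adjustments. After subtraction of block and of neighbour medians, Stmn3 had log2 ratios of 1.61 and 1.92 and Krt12 of 1.62 and 1.46. Both then lay above Septin3, with 1.45 and 1.32. The remaining 5 fell under 2-fold under at least 1 of them. They were the complement-activating lectin Mbl2 at 2.20-fold, the adaptor subunit Ap3b1 at 2.17-fold, the cornified envelope protein Sprr2a1 at 2.16-fold, the insulin-family peptide Insl5 at 2.03-fold and Ms4a2 at 2.03-fold. The name beside the Ms4a2 spot reads member 1 of the family, so the identity of that probe is uncertain.

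Among the 18 genes at least 2-fold lower with TGF-beta1, the microfibril protein Fbn2 was 2.76-fold lower, from 488 to 177. Chek2, a kinase of the DNA damage response, was 2.68-fold lower and the motor protein Myo9b 2.51-fold lower. A probe that the file names myxovirus (influenza virus) resistance 1, an interferon-induced antiviral gene, went from 290 to 116, a log2 ratio of -1.32. Nfkbia, the inhibitor that holds NF-kappaB in the cytoplasm, was 2.26-fold lower. The iron storage protein Fth1 was 2.17-fold lower, the tubulin Tuba4a 2.32-fold lower and the vomeronasal receptor Vmn2r122 2.42-fold lower. Tubulin and vomeronasal receptor genes have close relatives, and signal shared between relatives was not separated. All of these, with Clcn7, kept at least a 2-fold difference under the 3 position adjustments, as did 12 of the 18 in all. Ptprn at 2.28-fold, the urate transporter Slc22a12 at 2.18-fold and the aggrecan-degrading protease Adamts5 at 2.14-fold did not keep it under at least 1 of them.

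Genes above the threshold on 1 array only were given lower bounds. On the untreated array alone, Ibsp, the bone sialoprotein of mineralizing matrix, had a signal of 240 against 47.9 with TGF-beta1, at least 2.74-fold lower. The vesicle protein Syngr1 was at least 3.36-fold lower, the chemokine Pf4 at least 2.32-fold lower, the angiogenic ligand Angpt1 at least 1.98-fold lower and Prg2 at least 1.91-fold lower. On the treated array alone, the lipid kinase Dgke was at least 2.19-fold higher. Psg17 was at least 1.95-fold higher, Zp3 at least 1.82-fold higher, the amino acid transporter Slc7a10 at least 1.64-fold higher and the translation inhibitor Pdcd4 at least 1.63-fold higher. Of 200 such genes, 1 had a bound of at least 2-fold higher and 3 of at least 2-fold lower, and these 4 kept it under the 3 position adjustments.

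Osteoblast genes went both ways. Of 12 genes of the osteoblast differentiation list on the array, 5 were above the threshold on at least 1 array. Besides Ibsp, the adhesion molecule Cdh11 was at least 1.62-fold lower. Bglap, which encodes osteocalcin, had 846 untreated and 840 treated, a log2 ratio of -0.01. Alpl, the alkaline phosphatase of mineralization, had 94.1 and 124, a log2 ratio of 0.39, and the pyrophosphate transporter Ank was above the threshold on the treated array only. The Bglap probe was not separated from the near-identical copies of this gene. The list's median log2 ratio was -0.01 and lay at percentile 46.2 of random lists, and its mean was -0.45. Of the genes named in advance, Smad7, Col1a1, Runx2 and Spp1 were matched to 0 probes and are not analysed here.

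Genes of the extracellular matrix had lower signals with TGF-beta1 in the deposited values, and part of this followed place on the array. Of 12 members of the collagens and matrix list above the threshold on at least 1 array, 10 were lower and 2 higher by their measured ratio, or 9 and 3 after quantile normalization or loess, and 7 and 5 after subtraction of neighbour medians. Elastin, Eln, went from 947 to 495, 1.91-fold lower, but its log2 ratio of -0.94 became -0.20 after subtraction of the median of its block, C4. Lumican, Lum, and fibulin 2, Fbln2, were above the threshold on the untreated array only and were at least 1.18-fold and at least 1.16-fold lower. Fbln2 also lay in block C4, and its measured log2 ratio of -0.75 became -0.013 after subtraction of the block median and 0.019 after that of the neighbours. Chosen after their values were seen, Sparc, in block D4, had a log2 ratio of -0.58 that became 0.036 after subtraction of the block median and 0.013 after that of the neighbours, and Col1a2, an abundant chain of type I collagen, had 1174 and 1132, a log2 ratio of -0.05. The list's median log2 ratio was -0.37, at percentile 3.02 of random lists, and 1 member, Fbn2, passed 2-fold. With the 4 members above the threshold on 1 array at their bound, the median was -0.18, at percentile 3.12, but over the 8 members above it on both arrays it was -0.13, at percentile 15.1. Over all 19 members on the array, above the threshold or not, it was -0.32, at percentile 1.225. Of the 12 members, 3 lay in the 5 blocks of the array with the lowest ratios, and over the other 9 the median was -0.11, at percentile 34.1. It became -0.06, at percentile 26.8, after subtraction of block medians, and -0.12, at percentile 14.6, after subtraction of neighbour medians. In the list of matrix assembly and collagen processing 5 genes were above the threshold. Lox, the enzyme that cross-links collagen and elastin, had 354 untreated and 608 treated, 1.72-fold higher. Fkbp10, a collagen chaperone, had a log2 ratio of 0.26, the hyaluronan synthase Has1 of -0.27 and the procollagen enhancer Pcolce of -0.32. This list had a median of -0.21, at percentile 18.5, and a mean of 0.05, so that the median and the mean differed in sign.

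**Figure D2:**
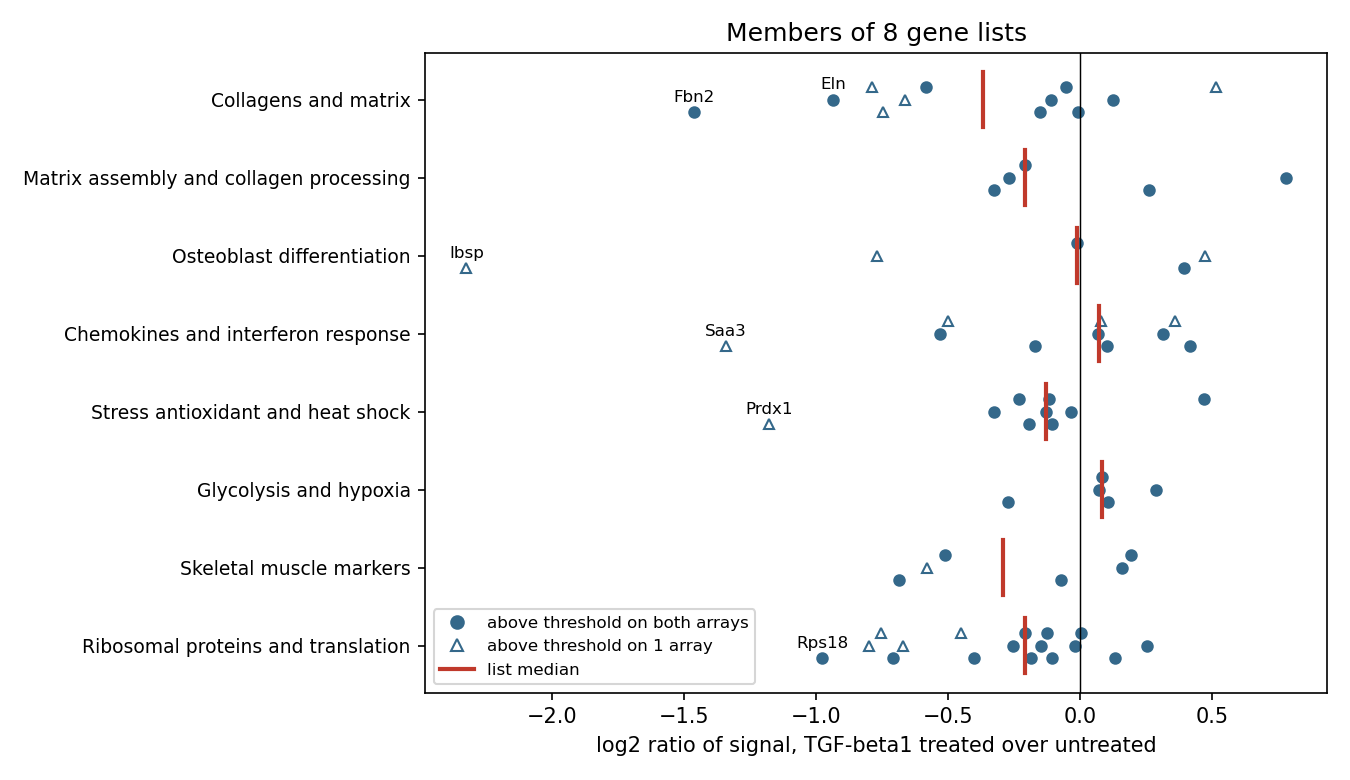
Log2 ratio of signal, TGF-beta1 treated over untreated (x axis), for each detected member of the 8 lists with at least 5 such members (rows). Filled circles are genes above the threshold on both arrays, open triangles genes above it on 1 array only, whose measured ratio is not a bound, and red bars list medians; the collagens and matrix list has the lowest median, -0.37, and Ibsp the lowest single value, -2.32.

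Single genes of BMP and Wnt signalling had higher signals, without a common direction in the Wnt list in the deposited values. Grem1, a secreted BMP antagonist, had 421 untreated and 814 treated, 1.93-fold higher. Tgfb3, a TGF-beta ligand, was 1.36-fold higher, and Nog, another BMP antagonist, had a log2 ratio of 0.13. These were the 3 detected members of 9 on the array in the list of TGF-beta and BMP ligands, receptors and Smads, and their median was 0.44. Tgfb3 lay in block L1, and its log2 ratio of 0.44 became 0.68 and 0.66 after subtraction of block and of neighbour medians. That of Grem1 fell from 0.95 to 0.72 and 0.70, and that of Nog fell to 0.07 and 0.08. Lrp6, a Wnt co-receptor, was 1.87-fold higher, from 315 to 589. In the Wnt list of 4 detected members, Tcf7l2 had a log2 ratio of 0.17 and Tcf7l1 of -0.37, both in block D4. After subtraction of the block median these became 0.79 and 0.25, so that the direction of Tcf7l1 turned. Axin2, a Wnt target, was above the threshold on the untreated array only. By measured ratios 2 members were higher and 2 lower, or 3 and 1 after subtraction of block or neighbour medians. The list's measured median of -0.10 became 0.08 with Axin2 at its bound, 0.46 after subtraction of block medians and 0.74 after that of neighbour medians. Of 12 TGF-beta early targets and feedback genes on the array, 4 were detected, with a median of 0.06 and a mean of -0.03 when members above the threshold on 1 array were set at their bound. Ccn2, a matricellular TGF-beta target, had 107 and 106, a log2 ratio of -0.02. Tgif1 had a log2 ratio of 0.17, the cell cycle inhibitor Cdkn2b was at least 1.34-fold lower and Ltbp3 at least 1.10-fold higher.

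The 3 actin and smooth muscle genes above the threshold on both arrays differed by less than 1.5-fold. Acta2, the smooth muscle actin, had 146 untreated and 179 treated, a log2 ratio of 0.30. Calponin 1, Cnn1, had a log2 ratio of 0.22 and profilin 1, Pfn1, of -0.30, while Actg1 was above the threshold on the untreated array only. With Actg1 at its bound, the median of these 4 members of the contractile and actin list was 0.04. Of proteases and inhibitors, 4 were detected, with a median of -0.08 when the 2 above the threshold on 1 array were set at their bound. Timp1, an inhibitor of matrix metalloproteases, had a log2 ratio of 0.27 and Adam17 of -0.29. Serpinf1 and the cysteine protease Ctsk, with at least 1.02-fold and at least 1.09-fold lower, were above the threshold on the untreated array only. Of growth factors and the IGF system, Fgf1 had a log2 ratio of 0.40, Bdnf of -0.25 and Vegfb of -0.31, and the median of these 3 was -0.25.

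Most detected members of the lists of protein synthesis and of stress defence had lower signals, but both medians over detected members lay between the 5th and the 95th percentile of random lists. Of 17 detected members of the ribosomal proteins and translation list, 14 were lower and 3 higher, or 15 and 2 after division by the total signal. Their median log2 ratio was -0.21, at percentile 10.5, or -0.13 with the 4 members above the threshold on 1 array at their bound. It became -0.10, at percentile 17.035, after subtraction of block medians and -0.083, at percentile 20.6, after that of neighbour medians. It lay under the 5th percentile over all 23 members on the array, at -0.25 and percentile 2.46, and with the offset, at -0.16 and percentile 4.865. Rps18 was 1.97-fold lower, from 247 to 125, and Rpl19 was at least 1.63-fold lower, or at least 1.14-fold after subtraction of the neighbours' median. The initiation factor Eif4e was 1.63-fold lower, but it lay in block C4, and its log2 ratio became 0.026 after subtraction of the block median and -0.067 after that of the neighbours. Of 9 genes of the stress, antioxidant and heat shock list, 8 were lower and 1 higher, with a median of -0.13 at percentile 17.04, which became -0.19 at percentile 6.02 and -0.25 at percentile 4.47 after subtraction of block and of neighbour medians. The peroxidase Prdx1 was at least 1.22-fold lower, the peroxidase Prdx2 had a log2 ratio of 0.47, the metallothionein Mt3 of -0.33 and the unfolded protein response factor Xbp1, in block E4, of -0.23, which turned to 0.21 after subtraction of the block median. After subtraction of block medians, 11 of the 17 and 7 of the 9 were lower, and after that of neighbour medians 11 and 6.

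Chemokine and interferon genes went both ways. Of 10 detected members 6 were higher and 4 lower, or 5 and 5 after loess. The list's median was 0.07, at percentile 69.4, and its mean was -0.12, so that they differed in sign. With 4 members at their bound they were 0.03 and -0.05. Saa3, an acute-phase protein, was at least 1.69-fold lower and the chemokine Ccl2 at least 1.04-fold lower. B2m, the light chain of class I molecules, had a log2 ratio of -0.53 and Irf9, an interferon signal transducer, of 0.42. Probes without a matched symbol could not enter any list. The interferon-induced probe named myxovirus resistance 1, at -1.32, was such a probe and is not in these counts. Of 5 detected genes of glycolysis and hypoxia, 4 were higher and 1 lower, with a median of 0.08 at percentile 66.0, but 1 was higher and 4 lower, with a median of -0.06, after subtraction of block medians, and 2 and 3, with a median of -0.08, after that of neighbour medians. Hk2 had a log2 ratio of 0.29, Pkm of 0.11, Aldoa of 0.08 and Pfkl of -0.27. Several lists had 1 detected member. Of cell cycle and DNA replication genes this was Birc5, the mitotic protein survivin, with a log2 ratio of 0.44 that became 0.19 after subtraction of the block median and 0.039 after that of the neighbours. Of apoptosis genes it was Gadd45b at -0.57, of immediate early and AP-1 genes Fosl1 at -0.10, and of integrins and adhesion genes Itga5 at 0.16, or 0.61 after subtraction of its block median. Of osteoclast-regulating factors it was Ccl2, which the chemokine list also holds.

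Markers of other cell types were measured on the same arrays, with few members detected in most lists. A signal above the threshold does not by itself show that such cells were present, since probe specificity was not tested. Of 9 skeletal muscle markers on the array 6 were detected, among them Tnnc2 with 808 untreated and 502 treated, 1.61-fold lower, and Myod1 with 646 and 739. Casq1 had a log2 ratio of -0.51 and Tnnc1 was at least 1.25-fold lower. The median of the muscle list was -0.29, at percentile 7.44, and became -0.19 with Tnnc1 at its bound, -0.07 among members above the threshold on both arrays and -0.09 after subtraction of neighbour medians. Without blocks B4 to F4 it stayed -0.29, at percentile 4.99. Of 8 adipocyte markers 4 were detected, with a median of 0.02 and a mean of -0.09, so that they differed in sign. By measured ratios 3 were higher and 1 lower, but all 4 were higher, with medians of 0.47 and 0.43, after subtraction of block and of neighbour medians, and the median was 0.084 under the additive adjustment. Acsl1, in block C4, had 2094 and 1403, a log2 ratio of -0.58 that turned to 0.16 after subtraction of the block median. Cfd had a log2 ratio of 0.18, Slc2a4 of 0.04 and Scd1 of 0.01, and these became 0.54, 0.72 and 0.40 after subtraction of block medians. The chondrocyte transcription factors Sox5 and Sox6 had log2 ratios of -0.43 and -0.21, with a median of -0.32, and were 2 of 9 on the array. The median was -0.16 after subtraction of block medians and -0.099 after that of neighbour medians, where Sox6 turned to 0.022. Of 16 macrophage and blood cell markers 3 were detected, Tyrobp with 481 and 687, H2-Eb1 with 671 and 679, and Cd79b above the threshold on the treated array only, with a median log2 ratio of 0.09 when Cd79b was set at its bound. The measured ratio of Cd79b turned from 0.12 to -0.14 after subtraction of the block median. Ctsk was the 1 osteoclast marker detected of 5, Ly6c1 the 1 endothelial marker of 8 with a log2 ratio of -0.11, and Syn1 the 1 neuronal or epithelial marker of 11, with 786 and 1109. Syn1 lay in block E4, and its log2 ratio of 0.50 became 0.94 and 0.95 after subtraction of block and of neighbour medians.

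The ratio also followed place on the array. Among probes under the threshold on both arrays, the 5 neighbouring blocks B4 to F4 had a median log2 ratio of -0.77, against -0.09 elsewhere. Other blocks were low as well, with medians of -0.56 in B1 and C1, -0.52 in B3 and -0.41 in L1. In 11 of 12 block letters the lowest median ratio was in block number 4. The signals themselves followed place on both arrays. Among probes under the threshold, the lowest median signal was in block number 4 in 12 of 12 letters on the untreated array. The same held in 12 of 12 on the treated array. Values elsewhere, and those without blocks B4 to F4, therefore still hold low blocks. The medians of the 48 blocks spanned 1.22 on the log2 scale, against at most 0.51 in 1000 shuffles of the block labels. Among genes above the threshold on both arrays the medians were -0.15 in blocks B4 to F4 and 0.05 elsewhere. Of the 18 genes at least 2-fold lower, 3 (16.7%) lay in blocks B4 to F4, Slc22a12, Adamts5 and Stim1. Stim1 was chosen after its values were seen. Of the 12 higher 1 (8.3%) did, Krt12, against 8.6% of all genes above the threshold on both arrays. Blocks of number 4 held 6 of the 18 lower genes (33.3%) and 2 of the 12 higher (16.7%), against 20.1% of all. Over all probes, whatever their signal, blocks of number 4 held 150 of 202 at least 2-fold lower (74.3%) and 7 of 23 higher (30.4%), against 25.3% of all. Syngr1 and Eln lay in blocks B4 to F4 too. Of the 75 genes above the threshold on both arrays that the naming rule took, 8 changed sign after subtraction of block or neighbour medians, namely Eif4e, Acsl1, Tcf7l1, Xbp1, Sox6, Bglap, Aldoa and Pkm, and 42 moved by more than the SD of the lambda spots, 0.20. In the authors' deposited table, the ratios of the 8 lambda control spots ranged from 0.749 to 1.18 with a median of 0.854. Those of 9 housekeeping genes ranged from 0.761 to 1.007 with a median of 0.918. All control spots lay in block E3, whose median log2 ratio over its gene probes was -0.24.

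**Figure D3:**
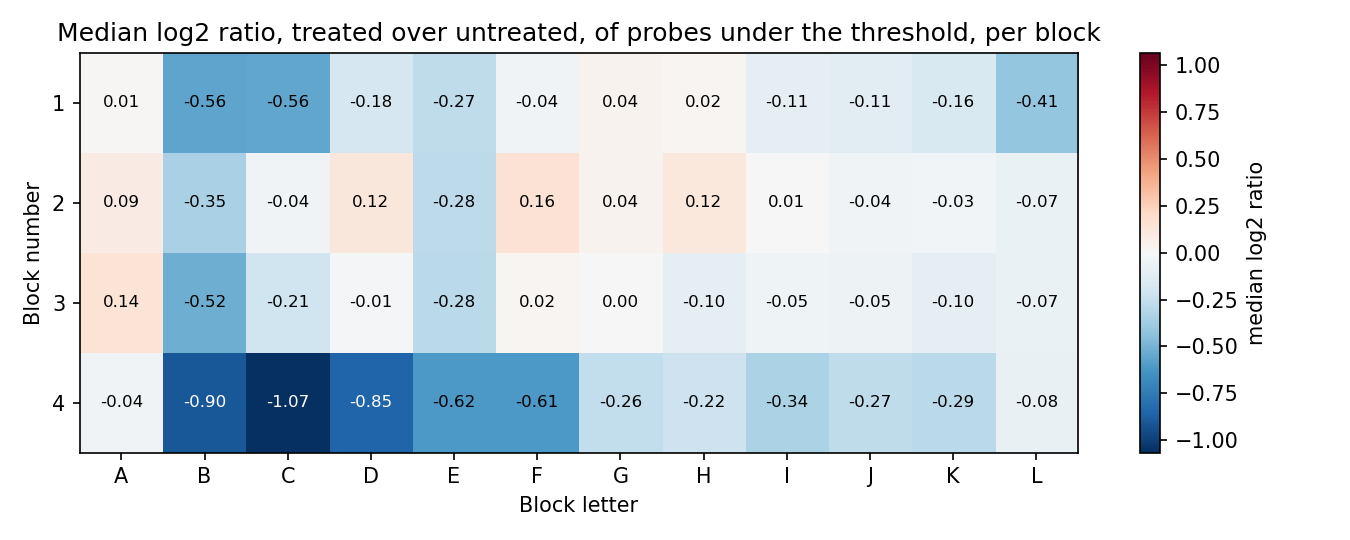
Median log2 ratio, TGF-beta1 treated over untreated, of probes under the threshold on both arrays, for each of the 48 blocks (letter on the x axis, number on the y axis; colour and printed value give the median). Blocks B4 to F4 hold the lowest medians, down to -1.07 in block C4.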

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

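The planned scalings (quantile, median of detected probes, total signal, loess) and the authors' deposited ratio left the counts of 12 higher and 18 lower within 1.5 times, at 9 to 12 and 18 to 27. They shifted the median of detected genes by at most 0.02. The position adjustments, the values without blocks B4 to F4 and the values of list members at their bound were chosen after the data were seen. An offset of 96.7 left 1 higher and 3 lower, since it shrinks every ratio by construction. At 1.5-fold there were 57 higher and 65 lower, and at 3-fold 1 and 1, again by construction. Counting genes detected on at least 1 array gave 34 lower, and genes at or above the array median on both arrays gave 32, since dimmer probes then count. The collagens and matrix list, at -0.37, moved to -0.064 with block medians subtracted, -0.12 with neighbour medians subtracted, -0.13 over members above the threshold on both arrays and -0.11 without blocks B4 to F4. The matrix assembly list moved to -0.0078 with neighbour medians subtracted. The skeletal muscle list moved to -0.088 with neighbour medians subtracted, -0.016 over all members and -0.073 over members above the threshold on both arrays. Other than as its construction shows, the cause was not tested. Of 111 list values 103 moved by less than 0.20, the SD of the lambda spots, as did 777 of 918 values of named genes. These totals hold settings that could hardly move a value by construction. They were the deposited ratio, division by the median or the total and, for lists, random lists not matched on signal. Of 102 named genes, 42 moved with block medians subtracted, 44 with neighbour medians subtracted and 47 with the offset. None of the called genes that the naming rule took changed sign. Signals without background correction and replicate spots were not run because none were used here, and the series value table was the main value itself. Signal over background limits the lists, since 2762 of 3757 probes were under the threshold on both arrays. No paired analysis was possible because each group held 1 sample.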

Other observations

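The tests of explanations and the position adjustments in this part were chosen after the results were seen, while the list percentiles over detected members and over members above the threshold on both arrays were planned. The brightest probe on both arrays belonged to Selenow, a small selenoprotein, with 3586 untreated and 4652 treated. Next by mean signal came Msc, a basic helix-loop-helix repressor, with 2730 and 4485, and Cyp46a1, the cholesterol 24-hydroxylase, with 2618 and 3764. The poly(A)-binding protein Pabpc1 had 3266 and 2867, and Atp5b, a subunit of mitochondrial ATP synthase, had 2086 and 1837. Among the 20 brightest probes were also genes best known from other tissues, such as Foxd3 with 2554 and 3419, a neural crest transcription factor, and Zap70 with 2440 and 3131, a T cell kinase. The water channel Aqp8 had 2472 and 2252. Whether these bright signals came from the named genes alone was not tested. These genes were chosen after their values were seen, as were those in the next paragraph.

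Several bright genes had ratios between 1.5-fold and 2-fold. Il1rl1, the receptor of interleukin 33, had 2056 untreated and 3780 treated, a log2 ratio of 0.88. Wbp1 had a log2 ratio of 0.94, the T-box factor Tbx21 of 0.89, the carnitine and cation transporter Slc22a4 of 0.88 and angiotensinogen, Agt, of 0.81. On the lower side, the growth factor Fgf17 had a log2 ratio of -0.96, the histone deacetylase Hdac1 of -0.94, the lipogenic protein Thrsp of -0.93 and the transcription factor Zbtb7b of -0.93, from 1790 to 940. Fgf17 lay in block C4, whose median log2 ratio over all its probes was -0.84. Of the 18 genes at least 2-fold lower, those outside the naming rule were Hnrnpa1 at -1.09, Tuba3a at -1.08, Cd93 at -1.06, Ndrg2 at -1.04, Nsg2 at -1.03 and Stim1 at -1.01. Tuba3a, Cd93 and Ndrg2 stayed at least 2-fold lower under all 3 position adjustments, while Hnrnpa1, Nsg2 and Stim1 did not. Block K1 held 4 of the 18, namely Vmn2r122, Tuba4a, Tuba3a and Fth1, and its median log2 ratio was -0.14.

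The ratios of treated over untreated signal were low in the neighbouring blocks B4 to F4. Dim probes had low signals in blocks of number 4 on the untreated array too. For the low ratios, expression of the genes spotted in B4 to F4 is argued against as the whole cause. The block medians of probes under the threshold spanned 1.22 and no shuffle exceeded 0.51. A fixed difference in local background is argued against as the whole cause too, because after the loss of 9.86 units seen in dim probes was added back, the 18 probes with a mean signal of 400 or more still lay -0.51 below those elsewhere, where random sets of probes lay between -0.27 and 0.22. A single scaling factor for all probes is argued against by the 30 with an untreated signal of 150 to 400, shifted by -0.20 (resampled -0.40 to -0.053) against -0.68 for dim probes, but the 18 of 400 or more were shifted by -0.46 (resampled -0.74 to -0.11), which leaves open a factor that they share with dim probes. A mixture of these, or uneven hybridisation or washing, may remain, and which of them applied was not tested.

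The lower signals of collagens and matrix genes, at percentile 3.02, may reflect place on the array, since the median lay at percentiles 14.6 and 26.8 once neighbour or block medians were subtracted, and at percentile 34.1 without blocks B4 to F4. With the additive adjustment it stayed at percentile 4.84. Members near the threshold may contribute as well, since the members above it on both arrays lay at percentile 15.1, although all 19 members, dim ones included, lay at percentile 1.225. An effect of TGF-beta1 cannot be told apart from a difference between arrays with 1 sample per group. Fbn2 kept a log2 ratio of -1.49 or lower under the 3 position adjustments, so place as these adjustments measure it does not account for that member.

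The lower signal of Ibsp is a candidate response to TGF-beta1. Place on the array, as the 3 position adjustments measure it, is argued against. The measured log2 ratio of -2.32 became -2.39, -2.19 and -2.31 under the block, neighbour and additive adjustments. The bound was 2.74-fold without them and at least 3.003-fold under each. That rise is not a result, since the adjustments also moved the lowest detected signal on which the bound rests. A smaller share of osteoblasts in the treated culture stays open. It would lower the other 4 detected members of the osteoblast list by about as much as Ibsp, with its bound of -1.45. Their median was 0.0015, with Ank and Cdh11 at their bound, but this median cannot decide. Ank was above the threshold on the treated array only, so its bound could not be negative. For Cdh11, the bound of -0.70 leaves room for a lower value. Its measured log2 ratio was -0.77, with a treated signal of 83.2, just under the threshold. Alpl, at 0.39, had an untreated signal of 94.1, near the threshold, so a large fall would have given only a small bound. Bglap, with 846 untreated and 840 treated, had room to fall and did not. It is a single gene, and its probe was not separated from near-identical copies. A single faulty spot cannot be told apart, since Ibsp had 1 probe on each array, and the treatment stays open as an untested hypothesis, since each group held 1 sample.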
